A study of Caenorhabditis elegans with 6 samples.

How the data were processed

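Total RNA of whole Caenorhabditis elegans worms was profiled in 6 libraries: 3 of the wild-type strain and 3 of a strain in which the circular RNA of crh-1 is knocked out, crh-1(syb385). The worms were day 1 adults kept at 20 °C on 25 µM FUdR, an inhibitor of DNA synthesis that stops progeny, and were collected over a 30 µm mesh. Libraries were made from 1 µg of total RNA with a stranded total RNA kit that removes rRNA, per the labels' protocols. The labels call the replicates independent and give both genotypes the numbers 1 to 3.

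The deposited table holds raw counts of fragments per gene. Per the file headers, the authors counted read pairs with featureCounts 1.5.0 over exons, summed by gene, with strand setting 2, on the Ensembl annotation of WBcel235. The command in the header has no option for reads that map to several places or overlap several genes, so such reads were left out of the counts; levels of near-identical gene copies, rRNA repeats included, are therefore uncertain. Per the submitters' processing notes, bcl2fastq 2.19, HISAT2 2.1.0 and DESeq2 1.26.0 were also used. A count of a gene pools reads from its linear and circular transcripts, which this table does not separate.

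The table has 46748 genes, of which 46449 have an entry in the reference annotation of the same build (Ensembl 115, WBcel235), which supplied names, biotypes and positions, and 299 do not; the latter kept their identifiers. Total counts per library ran from 38974777 to 47444165, and protein-coding counts from 14188050 to 35075781. No 2 libraries agreed within sampling noise: the smallest chi-square per degree of freedom between any 2 of them was 87.25. This shows only that no library is a copy of another. Each library was counted as a replicate because the labels call the replicates independent.

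Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered by filterByExpr with the group as factor (a minimum count of 10 and a minimum total of 15), which left 14354 genes, and scaled by TMM. Dispersions came from estimateDisp at default settings, and the quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest) compared knockout with wild type without covariates. The edgeR 4 method was requested explicitly, because the installed version defaults to the older one, which is among the alternatives. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Standard errors of log2 fold changes were computed as the fold change over the square root of F, and intervals are 95%. Levels are CPM (counts scaled to a common library size) on TMM-scaled library sizes.

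The 34 gene lists were written before the data were examined, as were the tests, the rule for named genes and most alternatives. Each list with at least 5 tested members was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists, beside camera with an estimated correlation and fry. The level of a list in a library is the mean over its genes of log2 CPM minus the gene's mean over the 6 libraries. Named genes are crh-1; then called genes with a mean of at least 1 CPM and no overlap between groups, or, with fewer than 5 of those, the 10 genes with the smallest p; and up to 4 genes with the smallest p of each list with a called member or a camera adjusted p under 0.05. rRNA genes were counted but not named. Tests of gene families and chromosomes were planned only for called genes and had none to run on.

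Replicate numbers were checked for pairing before the calls of the fits were compared. After subtraction of each group's mean, libraries with the same number correlated across genes with 0.65, 0.48 and 0.58, while the other pairs ran from -0.53 to 0.02. A group's deviations sum to 0, so high same-number correlations push the other pairs down, and the contrast is in part arithmetic. Every same-number correlation was over 0.1, so the numbers were taken to pair the samples. This is a working assumption, since the labels call the replicates independent and do not say what a number shares. Values from the fit with the replicate number as a block are given where they change a call.

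Alternatives were RLE, upper-quartile and no scaling factors, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 at default settings, limma-voom, the older edgeR method, no robust estimation, the replicate block, protein-coding genes only, rRNA genes left out, other thresholds, and each library left out in turn. Added after seeing the data were DESeq2 and the older edgeR method with the block, DESeq2 filtered at an alpha of 0.05, DESeq2 without each library, and camera with both the block and an estimated correlation. DESeq2's adjusted p was missing for 18 of the genes tested in edgeR, and these were not counted as calls.

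The fits were tested on simulated counts with the real means, library sizes and fitted spread, in which 200 genes were changed. A further 40 genes, taken as a list, were raised 1.5-fold and left out of the true and false calls. Camera at the preset correlation called this list (adjusted p = 9.37e-06) and 1 other list. Simulated genes were drawn independently of each other, so this result does not test camera on lists whose genes vary together. Over 14139 genes, the edgeR test recovered 4% of genes changed 2-fold, 48% at 4-fold, 82% at 8-fold and 92% at 16-fold for the comparison of knockout with wild type. It made 11 false calls beside 113 true ones, a false share of 8.9%. DESeq2 recovered 16% at 2-fold and 92% at 16-fold, with 59 false calls beside 132 true ones, a false share of 30.9%. The simulated libraries were independent, with the spread of the fit without the block, so they leave out the pairing of the replicate numbers and these shares are not estimates for the real calls. Figures were drawn with matplotlib 3.10.9.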

Results

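The series compared wild-type worms (strain N2) with worms of strain VDL786, which carries crh-1(syb385) and lacks the circular RNA made from crh-1, the gene of the CREB transcription factor. Each genotype had 3 libraries of whole day 1 adults. Total counts were 40626209, 42116982 and 40462731 in wild-type replicates 1 to 3 and 44520131, 38974777 and 47444165 in knockout replicates 1 to 3. rRNA genes took 36.41%, 34.1% and 25.98% of the counts in wild type and 34.53%, 58.54% and 22.86% in knockout. Knockout replicate 2 thus kept 14188050 protein-coding counts, against 24272152 to 35075781 in the other 5 libraries. mRNAs encoded by the mitochondrial genome made up 5.13% of its protein-coding counts and 0.59% to 2.22% of those of the others.

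**Figure D1:**
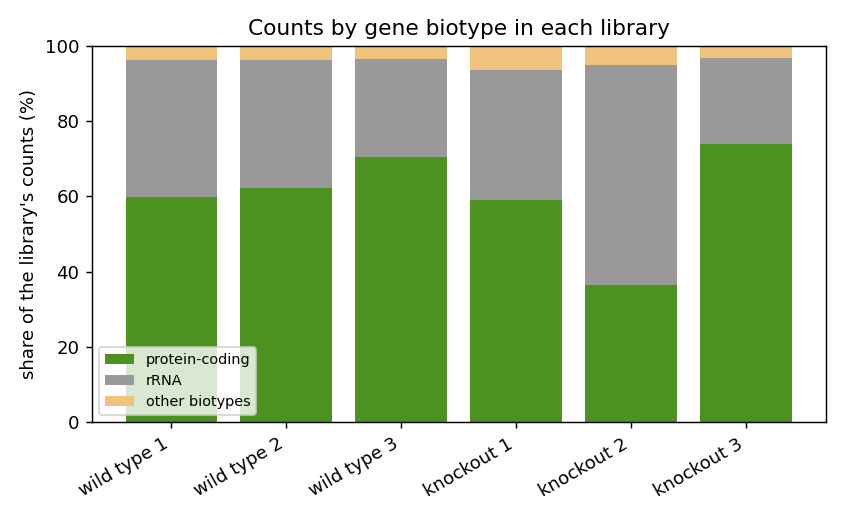
Bars give the percentage of each library's counts in protein-coding genes, rRNA genes and other biotypes, for 3 wild-type and 3 knockout libraries. Knockout replicate 2 has the largest rRNA share, 58.54%.

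The first comparison concerned the edited gene itself. The level of crh-1 (WBGene00000793; WBcel235 chromosome III, 11657738 to 11693837, plus strand, 11 annotated exon intervals in the count table) did not differ detectably between genotypes. It was 21.1 ± 2.63 CPM in wild type (SD, n = 3) and 19.8 ± 3.53 CPM in knockout (SD, n = 3). Single libraries had 20.6, 18.7 and 23.9 CPM in wild type and 17.9, 17.6 and 23.9 CPM in knockout. The log2 fold change was -0.09 (SE 0.25; edgeR quasi-likelihood adjusted p = 0.996). The 95% interval of the fold, knockout over wild type, ran from 0.63 to 1.4. Because linear and circular reads share exons, this count gives the gene as a whole, does not measure the circular RNA and is not a check of the genotype labels. Without wild-type replicate 3 the log2 fold change was 0.06, still far from the threshold. Within 500 kb of crh-1, 125 other genes were tested, with a median log2 fold change of 0.00 and a smallest adjusted p of 0.996. Of these, 1 had an unadjusted p under 0.05, Y41C4A.11 (III, 11719900 to 11723602), at 1.17 (SE 0.39; edgeR unadjusted p = 0.0166). Each of its knockout libraries lay above each wild-type library. The collagen gene col-95, named below, also lies in this window (III, 11703979 to 11705085). Whether such differences come from the edit or from the strain was not tested.

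The second comparison asked which genes differ when circ-crh-1 is missing. The 10 genes with the smallest p were all lower in the knockout, yet none passed the edgeR test, and the fold of each was smaller when wild-type replicate 2 was left out. F59B2.12 (III, 9017607 to 9020960) had 11.2 ± 9.84 CPM in wild type and 0.559 ± 0.306 CPM in knockout (SD, n = 3), a log2 fold change of -4.30 (SE 0.72; edgeR adjusted p = 0.996). The gene with the smallest p was C48B4.12 (III, 9597359 to 9598361), with 0.618 ± 0.308 CPM against 0.034 ± 0.0132 CPM (SD, n = 3), a log2 fold change of -4.13 (SE 0.64; edgeR adjusted p = 0.849). F46B6.13 (V, 9798926 to 9799179) had a log2 fold change of -5.04 (SE 0.93). The C-type lectin domain gene clec-208 had -4.18 (SE 0.81), F43C11.2 had -4.36 (SE 0.86), F26D2.16 had -3.40 (SE 0.66) and K12H6.9 had -3.45 (SE 0.61). Without wild-type replicate 2 the log2 fold changes were -3.65 for C48B4.12 and -3.72 for F46B6.13, and F59B2.12 (-3.30), clec-208 (-2.94), F43C11.2 (-3.23), F26D2.16 (-2.66) and K12H6.9 (-3.02) were then 6.34-fold to 9.85-fold lower. Knockout counts were low in most of these genes. C48B4.12 had 85 counts over the wild-type libraries and 4 over the knockout libraries, a depth-scaled ratio of 19.5 with a 95% counting interval of 7.35 to 73.3. F46B6.13 had 205 and 5 counts, a ratio of 37.7 (15.9 to 117), K12H6.9 had 76 and 6, a ratio of 11.6 (5.11 to 32.7), F43C11.2 had 174 and 7, a ratio of 22.8 (10.9 to 57.7), and clec-208 had 210 and 10, a ratio of 19.3 (10.3 to 40.8). The other 3 genes had 2 or 3 counts in knockout. The astacin protease gene nas-24 had 124 and 2 counts, a ratio of 57 (15.4 to 476). The lectin gene clec-137 had 72 and 3 counts, a ratio of 22.1 (7.25 to 109), and Y49F6B.6 had 60 and 3, a ratio of 18.4 (6 to 91.6). Without wild-type replicate 2 these 3 ratios were 26.2 (6.76 to 224) for nas-24, 9.92 (2.96 to 51.9) for clec-137 and 11.8 (3.6 to 61.1) for Y49F6B.6. These intervals cover counting error only.

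DESeq2, the alternative test, called 7 of these 10 genes, F59B2.12 (DESeq2 adjusted p = 8.74e-08), F46B6.13 (0.000857), F26D2.16 (0.00128), clec-208 (0.00171), F43C11.2 (0.00363), nas-24 (0.00911) and C48B4.12 (0.0262), and did not call K12H6.9 (0.0756), clec-137 (0.109) or Y49F6B.6 (0.182). Without wild-type replicate 2, F59B2.12 was the only 1 of the 10 that DESeq2 called (adjusted p = 0.000266). In all 10 of these genes each wild-type library lay above each knockout library, and wild-type replicate 2 was the highest. Because the genes were picked for a small p in these same libraries, the separation of the groups is in part a product of that choice. For F59B2.12 the wild-type values were 3.96, 22.4 and 7.18 CPM, so that the spread within wild type was almost as large as its mean. For F46B6.13 they were 0.486, 3.21 and 0.699 CPM, against 0.0424, 0.082 and 0.0188 CPM in knockout.

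**Figure D2:**
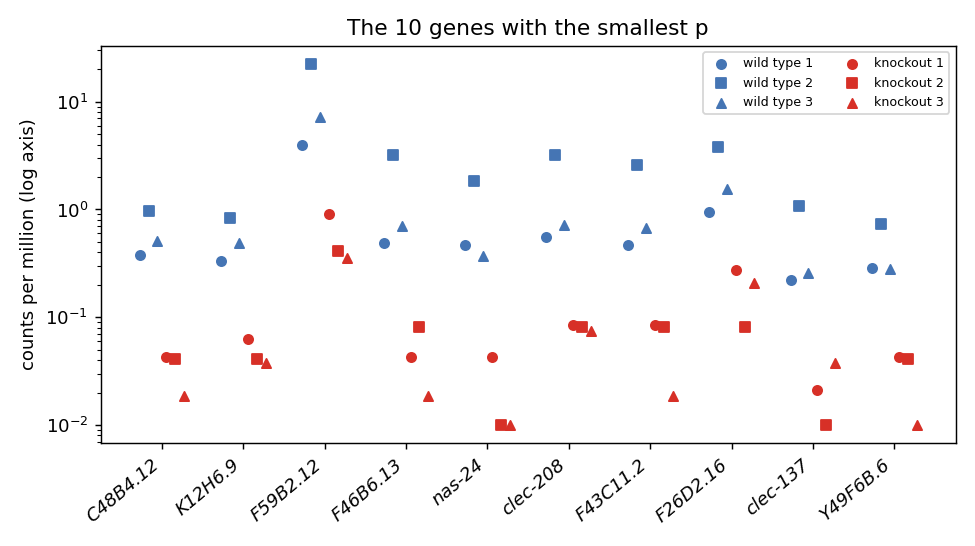
CPM on a log axis for the 10 genes with the smallest p, with 1 point per library (blue, wild type; red, knockout; circles, squares and triangles, replicates 1 to 3). Values of 0 are drawn at 0.01. Each wild-type point lies above each knockout point of the same gene, and wild-type replicate 2 is the highest.

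Of 14354 genes tested with edgeR, 0 were called, and 141 had an unadjusted p under 0.05 (58 higher and 83 lower in knockout), where 718 are expected if no gene differs. The shortfall is not evidence that no gene differs. Where the replicate numbers pair the samples, the fit without the block counts their shared variation as residual spread. DESeq2 called 31 genes, 1 higher and 30 lower, out of 16543 genes with a DESeq2 adjusted p, a larger set than that of edgeR. Among the lower genes, F56D2.8, srlf-26, fip-7, scl-7, F46A8.5, K03D3.5 and clec-217 had been removed by the edgeR filter. Without a filter edgeR tested 24822 genes and called 0. The DESeq2 count was 2 without wild-type replicate 2, 20 without knockout replicate 2 and 853 without knockout replicate 3, while edgeR called 0 genes without any 1 library. With the replicate number as a block, edgeR called 1 gene, F46B6.13, which was lower (edgeR adjusted p = 0.0466), with 684 genes at an unadjusted p under 0.05; the older edgeR method with the same block called 0, with 647 at an unadjusted p under 0.05. The groups did not overlap in 471 genes, or 3.28%, of which 247 were higher and 224 lower in knockout. Chance gives 10% for 3 against 3 if the 6 libraries are exchangeable, which fails where the replicate numbers pair the samples. The common biological coefficient of variation was 0.397, and 0.24 with the block.

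The third comparison took the gene lists. Camera with a preset correlation called 17 of the 34 lists, 6 lower and 11 higher in knockout. It called 7 without knockout replicate 2, 8 without wild-type replicate 3 and 11 without knockout replicate 1. With an estimated correlation it called 0 of 34, and fry called 0 of 34. The estimated inter-gene correlations of the called lists ran from 0.207 for innate immunity to 0.924 for mitochondrially encoded genes, against the preset 0.01. Genes of such a list vary together, so the shares of members that lie higher or lower are not counts of independent observations. In no list was a member called among all genes, and none was called adjusted over the list alone. For 15 of the called lists the adjusted p was 0.772 with an estimated correlation; for muscle it was 0.779 and for cuticle collagens 0.853. The smallest fry adjusted p was 0.907.

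The 6 called lists on the lower side were sperm, oocyte and germline, DNA replication and repair, proteasome subunits, Argonautes and small RNA pathway, and eggshell. Of 55 tested sperm genes, 54 had a negative log2 fold change, with a median of -0.58 (camera adjusted p = 3.89e-19; adjusted p = 0.772 with an estimated correlation). The members with the smallest p were nspd-9 at -1.84 (SE 0.67), nspd-4 at -1.26 (SE 0.63), spe-26 at -1.1 (SE 0.68) and spe-11 at -0.76 (SE 0.48). The list's level was 0.71, 0.84 and -0.16 in the wild-type libraries and 0.71, -0.40 and -1.70 in the knockout libraries, and without knockout replicate 3 the camera call was lost, with a median of -0.18 (adjusted p = 0.098). The median was -1.48 without knockout replicate 1 and -0.36 without wild-type replicate 1. The oocyte and germline list had 39 of 40 members on the lower side and a median of -0.27 (camera adjusted p = 2.83e-06; adjusted p = 0.772 with an estimated correlation), with syp-2 at -0.39 (SE 0.29) and gna-2 at -0.45 (SE 0.40). DNA replication and repair genes were lower in 35 of 35, with a median of -0.25, among them cku-80 at -0.35 (SE 0.32) and cdk-1 at -0.46 (SE 0.43). Proteasome subunits were lower in 33 of 33, with a median of -0.18, among them pas-2 at -0.34 (SE 0.28) and pas-5 at -0.31 (SE 0.26). Argonautes and small RNA pathway genes were lower in 32 of 37, with a median of -0.22, among them alg-3 at -0.74 (SE 0.54) and alg-4 at -0.75 (SE 0.62). Eggshell genes were lower in 10 of 12, with a median of -0.34, while perm-2 stood at 0.30 (SE 0.26). The last 4 lists had camera adjusted p of 2.83e-06, 0.00073, 0.000412 and 0.00831, in that order, and an adjusted p of 0.772 with an estimated correlation. Every list of this paragraph except sperm lost its camera call without knockout replicate 1 (medians from -0.07 to -0.01), without knockout replicate 2 (-0.04 to -0.01) and without wild-type replicate 3, where the medians turned positive, at 0.07 for oocyte and germline, 0.02 for DNA replication, 0.09 for the proteasome, 0.10 for Argonautes and 0.06 for eggshell. Without knockout replicate 3 the same medians were -0.97, -0.85, -0.55, -0.66 and -1.23, and without wild-type replicate 1 those of oocyte and germline, DNA replication and eggshell were -0.42, -0.38 and -0.54. In the replicate 3 pair, the oocyte and germline level was 0.64 in wild type and 0.77 in knockout, against -0.24 and -0.74 in the replicate 1 pair. DNA replication, proteasome and eggshell lists were also higher in knockout in the replicate 3 pair, by 0.09, 0.07 and 0.15. The difference there was -0.01 for Argonautes and -1.54 for sperm.

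Lists of mitochondrially encoded genes, ribosomal RNAs, fatty acid metabolism and ribosomal proteins were on the higher side. Of 12 genes encoded by the mitochondrial genome, 11 had a positive log2 fold change, with a median of 0.90 (camera adjusted p = 2.83e-06; adjusted p = 0.772 with an estimated correlation). ATP6 stood at 1.82 (SE 0.83), ND4 at 1.11 (SE 0.59), CYTB at 1.05 (SE 0.57) and ND1 at 0.94 (SE 0.49). The level of this list was higher in knockout in 3 of 3 replicate pairs, by 0.24, 1.56 and 0.40. It was 1.44 in knockout replicate 2, the library with the largest rRNA share, and without that library the call was lost, with a median of 0.20 (adjusted p = 0.176). The ribosomal RNA list, with a median of 0.62 (camera adjusted p = 0.0485; adjusted p = 0.772 with an estimated correlation), turned to -0.23 without the same library. Fatty acid metabolism genes were higher in 44 of 50, with a median of 0.28 (camera adjusted p = 5.13e-06), among them the acyl-CoA synthetase gene acs-2 at 0.73 (SE 0.34) and ech-7 at 0.56 (SE 0.29). Ribosomal proteins were higher in 73 of 75, with a median of 0.17 (camera adjusted p = 5.25e-06), among them rpl-37 at 0.62 (SE 0.34) and rps-29 at 0.37 (SE 0.25). Both lists had an adjusted p of 0.772 with an estimated correlation, and neither lost its preset-correlation call when any 1 library was left out. The fatty acid median was 0.17 without knockout replicate 1, 0.42 without wild-type replicate 1 and 0.54 without knockout replicate 3, and that of ribosomal proteins was 0.36 without wild-type replicate 3. In the replicate 3 pair the knockout level was below that of wild type for both lists (differences of -0.12 and -0.02), so that 2 of 3 pairs were higher.

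The remaining called lists had medians from 0.18 to 0.31. Nuclear-encoded oxidative phosphorylation genes were higher in 33 of 36 (camera adjusted p = 0.00104), with cox-7C at 0.43 (SE 0.26) and gas-1 at 0.42 (SE 0.30). Neuropeptide genes were higher in 83 of 105 (camera adjusted p = 0.00117), although ins-31 stood at -2.32 (SE 0.77) and ins-19 at 3.11 (SE 1.42). Intestinal genes were higher in 24 of 28 (camera adjusted p = 0.00119), with the proteases cpr-5 at 0.56 (SE 0.37) and cpr-1 at 0.52 (SE 0.37). DAF-16 activated genes were higher in 18 of 22 (camera adjusted p = 0.00161), with nnt-1 at 0.61 (SE 0.30) and the superoxide dismutase gene sod-3 at 1.03 (SE 0.53). Muscle genes were higher in 30 of 35 (camera adjusted p = 0.0166), with cpn-3 at 0.51 (SE 0.39) and tni-3 at 0.40 (SE 0.31). Cuticle collagens were higher in 89 of 117 (camera adjusted p = 0.0178), with col-95 at 0.61 (SE 0.30) and col-89 at 1.25 (SE 0.73). Innate immunity genes were higher in 32 of 44 (camera adjusted p = 0.0343), with ilys-5 at 0.56 (SE 0.37) and dod-24 at 0.75 (SE 0.52). With an estimated correlation the adjusted p was 0.779 for muscle, 0.853 for cuticle collagens and 0.772 for the other 5 lists. Each of these 7 lists lost its preset-correlation call without at least 1 of the 6 libraries, and cuticle collagens also lost it with the replicate block (adjusted p = 0.0548). In the replicate 3 pair the knockout level was below that of wild type in all 7 lists. The differences ran from -0.48 for the intestine to -0.05 for neuropeptides, so that 2 of 3 pairs were higher in each list. The median was 0.10 for DAF-16 activated genes, 0.04 for the intestine and -0.14 for innate immunity without knockout replicate 1. Without knockout replicate 2 it was 0.00 for muscle and -0.02 for neuropeptides, and for nuclear oxidative phosphorylation it ran from 0.14 without wild-type replicate 2 to 0.35 without wild-type replicate 3. Without knockout replicate 1 the collagens turned to the lower side, with a median of -0.20 (camera adjusted p = 0.0261). On library totals alone, where the median of all genes was -0.21 instead of 0.02, the medians of muscle, nuclear oxidative phosphorylation, neuropeptides, ribosomal proteins and cuticle collagens were below 0 but above that of all genes. Those of the other higher lists shrank, to 0.01 for fatty acid metabolism and innate immunity, 0.03 for the intestine, 0.08 for DAF-16 activated genes, 0.14 for ribosomal RNAs and 0.44 for mitochondrially encoded genes, and those of the lower lists lay between -0.83 and -0.34.

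**Figure D3:**
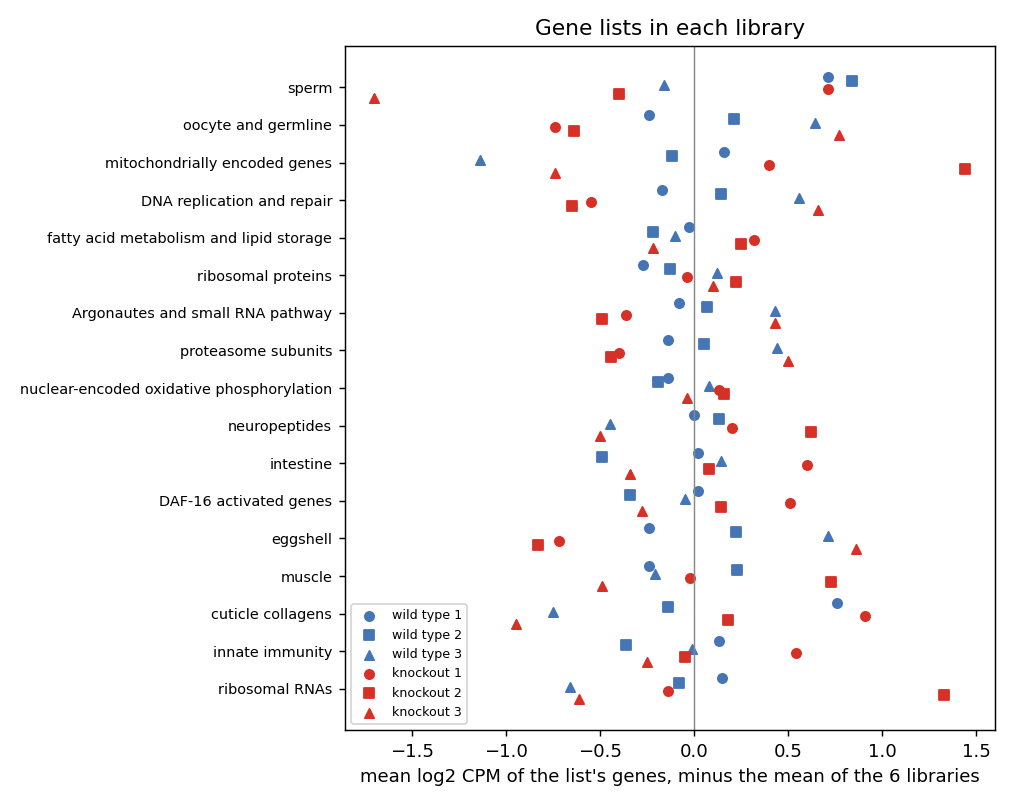
Level of each called list in each library, as the mean log2 CPM of its genes minus the mean over the 6 libraries (blue, wild type; red, knockout; circles, squares and triangles, replicates 1 to 3). Cuticle collagens are at 0.76 and 0.91 in the replicate 1 pair and at -0.75 and -0.95 in the replicate 3 pair.

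The 17 other lists had camera adjusted p from 0.0526 to 0.911. The CREB pathway, the list closest to crh-1, had 12 of 18 members on the higher side and a median of 0.12 (camera adjusted p = 0.53). Intracellular pathogen response, DAF-2 dependent genes repressed by DAF-16, molting and larval cuticle, hypodermis, hypoxia response, neuronal, cytosolic heat shock and coelomocyte lists had positive medians. Histones, early zygotic genes, vitellogenins, splicing regulators, insulin and longevity regulators, ER unfolded protein response, mitochondrial unfolded protein response and oxidative stress genes had negative ones. The mean was positive where the median was negative for splicing regulators, insulin and longevity regulators, the mitochondrial unfolded protein response and oxidative stress genes. With the block, 19 lists were called, among them intracellular pathogen response (adjusted p = 0.0441), DAF-2 dependent genes (adjusted p = 0.0401) and molting (adjusted p = 0.0441), and with the block and an estimated correlation 0 were.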

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

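The crh-1 level kept its side of the threshold under all alternatives run. Its log2 fold change ran from -0.29 to -0.02 across processing settings and from -0.24 to 0.06 with 1 library left out, where it changed sign without wild-type replicate 3 (0.056).

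The count of changed genes, 0 in edgeR (141 at an unadjusted p under 0.05), was 5 on library totals alone: F46B6.13, nas-24, C48B4.12, clec-208 and F43C11.2. It was 1 with the replicate block (0 with the block and the older method) and 31 with DESeq2. DESeq2 gave 35 with the replicate block, 24 of them shared with the 31, and 30 with filtering at an alpha of 0.05, both chosen after seeing the data. With each library left out in turn edgeR gave 0, while DESeq2 (chosen after seeing the data) gave 2 to 853. The other edgeR settings and limma-voom gave 0. The cause was not tested.

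The count of shifted lists, 17, ran from 16 to 20 across scaling, filter, test, feature and block settings and from 7 to 22 with 1 library left out. It was 7 without knockout replicate 2, 8 without wild-type replicate 3 and 11 without knockout replicate 1. It was 0 with an estimated correlation, 0 with that and the replicate block (chosen after seeing the data) and 0 with fry. Across processing settings 8 list calls were lost: eggshell with DESeq2 (adjusted p = 0.0731), muscle (0.184) and nuclear oxidative phosphorylation (0.0783) on library totals, ribosomal RNAs with RLE (0.0553), upper quartile (0.0622) and voom (0.102), and cuticle collagens without a filter (0.119) and with the block (0.0548). The block changed no other edgeR or camera call than those named. It did move medians. With the block the median went from -0.58 to -0.89 for sperm, from -0.27 to -0.43 for oocyte and germline and from -0.34 to -0.58 for eggshell. For cuticle collagens it shrank from 0.28 to 0.09 and for ribosomal RNAs from 0.62 to 0.31, while for ribosomal proteins it went from 0.17 to 0.18.

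With 1 library left out, 7 list results turned direction and 29 lost their call. The range of medians was -0.195 to 0.777 for cuticle collagens, -0.142 to 0.483 for innate immunity, 0.041 to 0.547 for the intestine, 0.002 to 0.597 for muscle, -0.015 to 0.516 for neuropeptides and -0.234 to 0.939 for ribosomal RNAs. Their turned values were 0.044 and -0.195 for collagens (without wild-type replicate 3 and knockout replicate 1), -0.142 for immunity and 0.041 for the intestine (without knockout replicate 1), and 0.002, -0.015 and -0.234 for muscle, neuropeptides and ribosomal RNAs (without knockout replicate 2). The camera direction compares a list with other genes, so it can differ from the sign of the median. The cause was not tested. Apart from crh-1, no gene checked among those named changed sign. At these depths, edgeR recovered 4% of genes changed 2-fold in simulated counts with the fitted spread, and 90% with a coefficient of variation of 0.1.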

Other observations

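The male gene list, the family test and the chromosome counts below, and the tests of depth, of rRNA share and of germline amount, were chosen after the results they bear on were seen; the male list was written before its own values were looked at.

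The 30 genes that DESeq2 called lower in knockout included more members of some gene families than their share. Of them, 15 carry a family name, among 8585 tested genes that do. C-type lectins (clec, 5 of 129 tested; Fisher exact adjusted p = 0.000264), trypsin-like proteases (try, 2 of 13; 0.0154), srlf (2 of 16; 0.0157), fipr (2 of 24; 0.0269) and astacin proteases (nas, 2 of 30; 0.0337) passed the one-sided test over 140 families. Beside those named above they include clec-197 at a log2 fold change of -4.43 (SE 0.83; DESeq2 adjusted p = 0.000377) and clec-219 at -4.45 (SE 0.82; DESeq2 adjusted p = 0.000377). Their normalized counts in wild-type replicates 1 to 3 were 42.1, 504.1 and 100.8, and 30.8, 254.7 and 49.9. Without wild-type replicate 2, DESeq2 called no member of these families. The Fisher test treats genes as independent draws, so its p-values do not measure replication across worms. Yet clec-207 and clec-208 lie close together (V, from 2096072 and 2097953), as do try-8 and try-13 (V, from 7452707 and 7440107). Chromosome V held 11 of the 30 lower genes, among 3283 tested genes (two-sided Fisher exact p = 0.0352, adjusted p = 0.246), and IV held 8, among 2825. No chromosome passed after adjustment. The 1 higher gene, the noncoding F31C3.14, had a log2 fold change of 1.97 (SE 0.5; DESeq2 adjusted p = 0.0391).

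All 30 lower genes were highest in wild-type replicate 2, by a median log2 difference of 2.33 from the mean of the other 2 wild-type libraries, and in all 30 each wild-type library lay above each knockout library. This separation of the groups follows in part from the choice of genes called lower in these same libraries. Without wild-type replicate 2, DESeq2 called 2 genes, F59B2.12 (lower) and W05H7.1 (higher), 1 of them shared with the 31; without knockout replicate 2 it called 20, and without knockout replicate 3 it called 853, of which 2 were shared. Lower coding depth in knockout is argued against as the whole cause: knockout replicates 1 and 3 had 0.998 and 1.33 times the mean protein-coding counts of wild type, 1.16 on average, and only knockout replicate 2 had fewer, 0.538 times. Males among the wild-type worms may contribute, since the male list of 12 genes was highest in wild-type replicate 2, with 7 of its 8 detected genes lower in knockout and a median log2 fold change of -1.02; this passed the bound of -1 set in advance by less than its error of 0.98, a margin asked for only after the value was seen, so it stays open. That error comes from the spread among the 8 detected genes and does not measure variation between libraries. The list's mean log2 CPM was -3.19, -1.68 and -2.54 in wild-type replicates 1 to 3 and -3.24, -2.83 and -3.05 in knockout replicates 1 to 3. Unlike the 30 genes, the male list was thus lower in wild-type replicate 1 than in knockout replicates 2 and 3. Its counts were low (pkd-2 had 1, 10 and 5 in wild type and 0, 0 and 0 in knockout; her-1 had 19, 45 and 20 against 26, 19 and 25), and the genotype, or another difference between the strains, stays open as untested.

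The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For the edgeR count the real split gave 0 genes, which each of the 10 splits matches by construction, so that count tests nothing; for DESeq2 it gave 31, and for the lists 17, and in each case 6 of the 10 splits, the real one included, gave as many. The highest other values were 2552, 3484 and 24, all from the split that sets wild-type replicate 1 and knockout replicates 1 and 2 against the rest. That split parts 1 replicate pair, that of replicate 2, and points to a structure of the samples other than genotype. The rRNA shares of wild-type replicate 1 and knockout replicates 1 and 2 were 36.41%, 34.53% and 58.54%. Those of wild-type replicates 2 and 3 and knockout replicate 3 were lower, at 34.1%, 25.98% and 22.86%. Oocyte and germline levels, in the same order, were -0.24, -0.74 and -0.64 against 0.21, 0.64 and 0.77. What sets these libraries apart was not tested. Among the 3 other splits that, like the real one, part all 3 pairs, edgeR called 0 in each, DESeq2 called 0 to 1 and 8 to 20 lists were shifted.

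In oocyte, DNA replication and cuticle collagen lists, both libraries of the replicate 1 pair lay on one side of the mean and both of the replicate 3 pair on the other, while the replicate 2 pair was split. Wild-type and knockout replicate 2 stood at 0.21 and -0.64 for oocyte and germline, 0.14 and -0.65 for DNA replication, 0.84 and -0.40 for sperm and -0.14 and 0.18 for collagens. From the replicate 1 pair to the replicate 3 pair, the oocyte and germline level differed by 1.2, DNA replication and repair by 0.97 and cuticle collagens by -1.69, and heat shock proteins stood at 0.81 and 1.08 in the replicate 2 pair against -0.17, -0.19, -0.86 and -0.67 in the others. For the replicate 1 and 3 pairs, a shared amount of germline against body tissue per collection stays open: the pair means of 4 of 4 body lists (muscle, neuronal, intestine and hypodermis) were lower in the replicate 3 pair, by 0.22 to 0.66, but within wild type this held for 2 of 4 lists only. Wild-type replicates 1 and 3 stood at 0.02 and 0.14 for the intestine and -0.24 and -0.21 for muscle, against 0.60 and -0.34, and -0.02 and -0.49, in knockout. The sperm list, also germline, differed by -1.64 in the opposite direction to the oocyte list. The rRNA share stays open as well: its Pearson r with the oocyte and germline level over 6 libraries was -0.75 (exact permutation p = 0.0472) and Spearman's rho -0.83 (exact permutation p = 0.0583), with r = -0.76 without the 2 libraries farthest from the median share, in the 1 relation computed. Both p-values treat the 6 libraries as exchangeable, which fails where the replicate numbers pair the samples, so neither can be read against the threshold of 0.05.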
